A study of Mus musculus with 20 samples.

How the data were processed

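Gene expression was measured by RNA sequencing of mouse cells during chemical reprogramming. The series held 20 samples, and 19 libraries were analysed: MEFs (1), untreated cells at days 16, 20, 24 and 28 and crotonic acid-treated cells at days 20, 24 and 28 (2 each), CiPS lines of the crotonic acid method (2) and of the three-step method (1), and 1 ES line. RNA was isolated with a Qiagen RNA mini kit and libraries were made with the NEBNext Ultra RNA kit, per the labels' protocols; whether strand was kept is not given in the sources used here. The library of the BrdU line was left out, since 1 of the 20 columns of per-sample values bore a name that no label gave, and that column was not used.

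The deposited count table held whole-number read counts per Ensembl gene for 19 usable libraries, made by the authors; aligner, counting tool, genome build and annotation are not given in the sources used here. The deposited FPKM table held values per kilobase of gene, scaled by the authors with a factor per library that differed from the column total; it left out genes with at most 1 count over all columns. From the counts, CPM values were computed with TMM factors, and from FPKM values log2(FPKM + 1) and log2(FPKM + 0.1) were computed. Of all identifiers 419 had no symbol. Total counts ran from 17.5e6 to 26.6e6 reads per library. Replicates differed by far more than counting: the chi-squared of replicate differences per degree of freedom was 5.18 in the crotonic acid lines and 101 at day 16, so depth set the precision only for genes of few counts. The biological coefficient of variation was 23.0% in the reprogramming fit and 22.2% with all libraries.

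Counts were tested in edgeR 4.0.16 under R 4.3.3 by the quasi-likelihood F test (filterByExpr with a minimum count of 10, TMM factors, 2-sided), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The 14 reprogramming libraries (7 groups of 2) were fitted together over 17387 genes, for the effect of crotonic acid at each day, its mean over 3 days, its difference between days 28 and 20, and the change from day 16. Comparisons with MEFs, ES cells and CiPS lines used a fit of all 19 libraries over 19597 genes, where the 3 CiPS lines formed 1 group; the lines by method were compared in a fit with separate groups of 2 and 1. The plan had counted 20 libraries and 4 CiPS lines, with the BrdU line in the second arm of that last comparison. A lone library was assumed to vary like the other groups. Folds against a group without counts are given as lower bounds from a floor of 3 counts over that group. Where a group had 1 to 3 counts, levels or a ratio with its exact 95% counting interval are given.

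Gene lists, 28 in number and fixed before the data were examined, were tested with camera in limma 3.58.1 (preset correlation 0.01, lists with at least 3 tested members, adjustment over lists within a comparison). Members past the threshold were counted over all genes and adjusted over the list alone. Each library was projected, as log2 CPM, on the difference between ES cells and MEFs, and treated and untreated positions were compared by an exact permutation of labels within days. Genes called on different days were compared by Fisher's exact test in each direction.

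Replicate numbers were checked for pairing before the fits were compared. Deviations from the group mean were correlated between every pair of groups: all 21 correlations lay between 0.258 and 0.578, so the planned fit with the replicate number as a block is given beside the other for the reprogramming libraries (biological coefficient of variation 14.3%). Between both replicate sets 5484 of 17387 genes differed.

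Alternatives fixed before the data were examined were RLE factors, total-count scaling, no filter on low counts, DESeq2 1.42.0 (Wald test), limma-voom, limma with a trend on FPKM with either pseudocount (mean FPKM of at least 1), a 2-fold threshold, a fit of the compared groups alone, each library left out in turn, the replicate block, and for lists an estimated correlation and fry. Added after the data were seen were fits without the day 16 libraries and fits without D20 + crotonic acid replicate 2 and D28 + crotonic acid replicate 1, each with and without the block. Leaving out single libraries could leave groups of 1.

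Named genes followed a rule: in each comparison the 8 largest changes up and the 8 largest down among called genes whose libraries did not overlap, with at least 5 CPM in the higher group; the 4 members with the smallest p of each list described; and a fixed set of pluripotency, endoderm, telomere, fibroblast and chromatin genes. Not every such gene is named, and some results are not reported here. Reads of genes with near-identical copies cannot be assigned safely, so Zscan4 and other 2-cell genes, H2-Q and Xlr genes and Rpl26 are uncertain one by one.

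The test was tried on simulated counts with 100 genes changed at each of 2 sizes, modelled on these libraries. The counts were drawn from the blocked fit, gene by gene, so a replicate effect was built in. The gain with the block therefore does not show that the block suits the real counts. At day 28 it found 28 of 100 genes at a log2 change of 1 and 70 at 2, and with the block 64 and 90, where 10 of 166 called genes were unchanged. For the mean over days it found 72 and 98, and with the block 90 and 100, where 16 of 216 were unchanged.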

Results

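The study followed gene expression while mouse embryonic fibroblasts (MEFs) were turned into pluripotent cells by small molecules alone, giving chemically induced pluripotent stem (CiPS) cells. Crotonic acid, a short-chain fatty acid whose CoA form is the donor for histone crotonylation, was added to some cultures at 6 to 8 mM from day 16 to day 28, and the stated question was how it promotes the formation of CiPS cells. The 19 libraries analysed here were 1 of MEFs, 2 each of untreated cells at days 16, 20, 24 and 28, 2 each of crotonic acid-treated cells at days 20, 24 and 28, 2 CiPS lines made with crotonic acid, 1 line made by the three-step method and 1 embryonic stem (ES) cell line of the same B6DBA strain. A CiPS line made by the BrdU method was not analysed here. Libraries held 17.5e6 to 26.6e6 counted reads over all Ensembl genes. Levels are counts scaled by library size (CPM, mean ± SD), and changes are log2 fold changes ± standard error with Benjamini-Hochberg adjusted p from edgeR's quasi-likelihood test. The labels did not say that paired libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical. MEFs, ES cells and the three-step line had 1 library each, and each lone sample was assumed to vary like the other groups. The groups, tests, 28 gene lists, alternatives and rule for named genes were fixed before the data were examined. Libraries with the same replicate number deviated together, so values from a fit with the replicate number as a block are given beside the genes and lists described where they changed a call or a count by over 1.5 times.

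The first comparison asked what the cells had become by day 16 of chemical treatment. Epithelial genes rose in 20 of the 22 measured members, and 1 fell. Epcam, an epithelial adhesion protein, stood at 278 ± 1.28 CPM at day 16 (n = 2) against 0.141 in MEFs, and E-cadherin (Cdh1) rose by 7.06 ± 0.52 to 120 ± 31.8 CPM (adjusted p = 1.65e-06). Genes of extraembryonic endoderm, the yolk sac lineage, rose in 20 of 26 members and fell in 1. The endoderm regulator Gata4 rose by 5.63 ± 0.66 to 626 ± 187 CPM (adjusted p = 4.39e-05), the laminin gene Lama1 rose by 6.28 ± 0.40 (adjusted p = 6.45e-07), and Foxa2, a pioneer factor of endoderm, rose by 8.10 ± 0.57. Sox17, another endoderm regulator, reached 423 ± 117 CPM from 0.141 in MEFs, a ratio of 3000 with a counting interval of 1020 to 14500. Gata6 rose by 1.46 ± 0.35 to 119 ± 3.31 CPM.

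Fibroblast identity was lower at day 16: 13 of 24 fibroblast genes fell and 11 did not pass. Col1a1, the main chain of type I collagen, fell by 4.70 ± 0.73 from 34210 CPM in MEFs to 1313 ± 1170 CPM (adjusted p = 0.000367), with a spread between both day 16 libraries nearly as large as their mean. Fibronectin (Fn1) fell by 2.64 ± 0.25 and Pdgfrb, a receptor of mesenchymal cells, fell by 4.27 ± 0.52, while Thy1 did not pass (457 ± 374 against 745 CPM, adjusted p = 0.395). Among the genes with the largest falls were the matrix genes Eln, from 5287 to 1.96 ± 1.22 CPM, Fmod, from 376 to 0.136 ± 0.129 CPM, and the tendon gene Tnmd, which was at least 2410-fold lower, since day 16 held no count (floor of 3 counts over the group). Genes of cholesterol synthesis fell in 17 of 21 members, with Cyp51, a sterol demethylase, at -1.93 ± 0.17. Macrophage genes, markers of a cell type that MEF cultures often hold, fell in 15 of 16 members, from 37.0 to 0.842 ± 1.13 CPM for the complement gene C1qa. Fga, a fibrinogen gene of liver, was at least 79.2-fold lower; it belonged to a set of liver transcripts seen in the MEF library and in 2 crotonic acid libraries.

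Some naive pluripotency genes were on at day 16. Of 26 naive pluripotency genes 12 rose, 2 fell and 12 did not pass. The threonine dehydrogenase Tdh was at least 482-fold higher. Sall4, a factor of pluripotent and endoderm cells that is counted in the endoderm list, was at least 1090-fold higher (153 ± 36.7 CPM against 0). Sox2 rose by 4.83 ± 0.40 to 37.7 ± 13.8 CPM, whereas Klf2 fell by 5.17 ± 0.42 and Nanog fell by 1.94 ± 0.52 to 0.364 CPM. Pou5f1, which encodes OCT4, had no count in either group, nor had Zscan4c, a gene of the 2-cell embryo. At day 16 the naive genes Dppa2 and Zfp42 had 0 and 2 counts over both libraries. Tert, the catalytic subunit of telomerase, stood at 5.46 ± 0.249 CPM against 5.13 in MEFs (adjusted p = 0.879), and the telomere protein gene Terf1 at 24.7 ± 5.71 against 17.5 (adjusted p = 0.183). The de novo methyltransferase gene Dnmt3b rose by 2.88 ± 0.64. Genes with the largest rises included the protease gene Tmprss2 (at least 1590-fold) and the epithelial factor Elf3 (at least 1090-fold). Members of the trophoblast list rose in 9 of 14 cases and of the neural list in 11 of 19, with 1 lower, among them the trophoblast factor Cdx2 at 15.7 ± 9.94 CPM and the neural factor Pax6 at 16.9 ± 7.76 CPM. Of 22 imprinted genes 8 fell and 2 rose, among them Peg10, a placental gene, by 5.19 ± 0.68.

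In all, 3416 of 19597 tested genes rose and 2995 fell from MEFs to day 16. Camera called 9 lists with its preset correlation: epithelial (adjusted p = 7.85e-24), extraembryonic endoderm (1.42e-14), naive pluripotency (4.25e-05), trophoblast (7.23e-05) and neural (0.000327) up, and cholesterol synthesis (6.65e-11), fibroblast (2.88e-09), macrophage (4.74e-07) and imprinted genes (0.0247) down. None of the 9 held with an estimated correlation, where the epithelial, endoderm, cholesterol, trophoblast and neural lists had an adjusted p = 0.0952, the naive, macrophage and imprinted lists 0.149 and the fibroblast list 0.242. Scaling by total counts alone put the median log2 change of all genes at 0.365, against 0.03 with TMM factors. It gave 5345 higher and 1812 lower genes, so the split into higher and lower depends on the scaling. With only the compared libraries in the fit, 1821 genes were called.

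The next comparison followed untreated cultures from day 16 to day 28. Pou5f1 had no count at day 16 and 12.3 ± 3.59 CPM at day 28, at least 178-fold higher (adjusted p = 0.000424). Dppa5a, a marker of naive pluripotent cells, rose by 10.17 ± 0.58 to 210 ± 13.4 CPM (adjusted p = 6.75e-06), and Dppa2, a chromatin factor of pluripotent cells, was at least 74-fold higher. In total 11 of 23 naive pluripotency genes rose and none fell, while 17 rose and 1 fell when adjusted over the list alone; with the block 15 rose and 1 fell over all genes. Nanog, at 0.854 ± 0.199 CPM against 0.364 (adjusted p = 0.109), and Sox2, at 60.9 ± 12.7 against 37.7 ± 13.8 (adjusted p = 0.0554), did not pass; Sox2 passed with the block (adjusted p = 0.0231). Germline genes rose in 19 of 22 members: the oocyte and sperm gene Dazl by 7.16 ± 0.66 to 19.7 ± 4.55 CPM, the PIWI gene Piwil2 by 5.71 ± 0.50, and the homeobox gene Rhox9 by 7.48 ± 0.53. The germ cell factor Sohlh2 was at least 161-fold higher, and the meiotic chaperone gene Fkbp6 rose from 1 count to 46.2 ± 2.70 CPM, a ratio of 2020 with a counting interval of 363 to 80000.

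Genes of the 2-cell embryo, which near-identical copies make uncertain one by one, rose in 18 of 23 members by day 28. Zscan4c went from no count to 3.58 ± 1.29 CPM, at least 51.5-fold higher, and Zscan4d to 2.45 ± 1.36 CPM. Terf1 rose by 0.82 ± 0.23 to 42.4 ± 5.79 CPM (adjusted p = 0.0319). Tert stood at 5.24 ± 1.22 CPM against 5.46 ± 0.249 (adjusted p = 0.978), and none of the 11 telomerase genes passed; with the block 1 rose. Interferon response genes rose in 5 of 21 members, including the antiviral gene Oasl2 by 2.39 ± 0.33, and with the block 10 rose and 1 fell. Among endoderm genes Lama1 rose by 0.97 ± 0.23, Lamb1 by 0.74 ± 0.17, Apoa1, an apolipoprotein gene, by 6.31 ± 1.65 and Gata6 by 0.89 ± 0.27, while the other 21 did not pass. With the block 13 rose, among them Gata4 by 0.36 ± 0.12 (adjusted p = 0.0413).

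Fibroblast genes fell in 14 of 24 members between day 16 and day 28 and 1 rose; with the block 19 fell and 2 rose. Col6a2 fell by 3.32 ± 0.38, the mesenchymal factor Twist1 by 3.30 ± 0.43 and Thy1 by 3.77 ± 0.57, while Col1a1 had 385 ± 307 CPM against 1313 ± 1170 (adjusted p = 0.101; with the block it fell, adjusted p = 0.017). Muscle genes fell in 7 of 16 members (10 with the block), such as the cardiac actin Actc1 by 4.08 ± 0.37, and neural genes fell in 5 of 15 with 2 higher, such as Elavl3 by 4.92 ± 0.53. Imprinted genes rose in 2 of 22 members and fell in 7, with the block in 5 and 9. Those that fell included the growth inhibitor Cdkn1c by 2.76 ± 0.18, the growth factor Igf2 by 3.20 ± 0.31, from 2885 ± 1540 to 302 ± 23.4 CPM, and the noncoding H19 by 2.81 ± 0.40. Of 21 cholesterol genes 5 fell and 1 rose (10 and 1 with the block), with the sterol dehydrogenase gene Nsdhl at -0.73 ± 0.17. The mesoderm factor T went from 5.29 ± 5.29 to 0.0678 ± 0.0959 CPM (232 and 3 counts).

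Altogether 1751 of 17387 tested genes rose and 1182 fell (n = 2 against 2), after 288 and 100 at day 20 (967 and 763 with the block) and 870 and 535 at day 24 (1918 and 1646 with the block). Camera called the naive (adjusted p = 7.26e-15) and germline (1.07e-27) lists up, also with an estimated correlation (adjusted p = 0.0474 for each). The calls of the 2-cell (up, 7.03e-14), interferon (up, 0.0012), fibroblast (down, 4.84e-09), muscle (down, 0.000153), imprinted (down, 0.000327), cholesterol (down, 0.00635) and neural (down, 0.0188) lists were lost, with an adjusted p = 0.198, 0.803, 0.48, 0.253, 0.1, 0.668 and 0.154 with an estimated correlation, in that order. With the block 2922 genes rose and 2472 fell, the neural call ended (adjusted p = 0.0654), and the endoderm list passed upward (0.0141) and the inflammation list downward (0.0232; adjusted p = 0.516 and 0.7 with an estimated correlation). Leaving out day 28 replicate 2 gave 1553 calls, and fitting only the 4 compared libraries gave 332 higher and 69 lower.

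**Figure D1:**
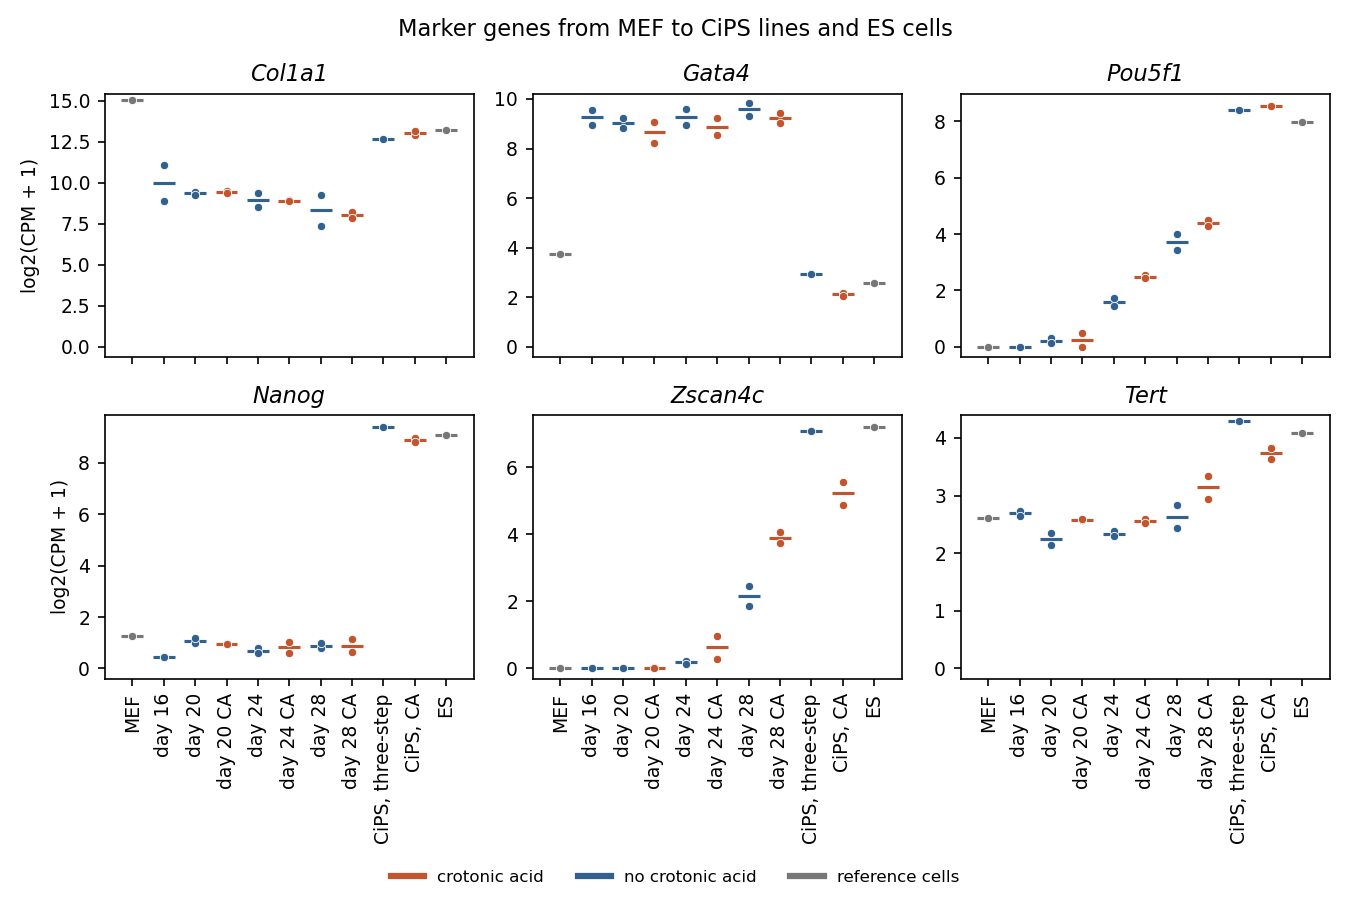
Levels of 6 genes as log2(CPM + 1) in 11 groups, with a point per library and a bar at each group mean: Col1a1 lies at 34210 CPM in MEFs, 385 CPM at day 28 and 7755 CPM on average in the 3 CiPS lines. Gata4 is at 626 CPM at day 16 and 4.50 CPM in CiPS lines, while Pou5f1, Nanog, Zscan4c and Tert are highest in CiPS or ES cells.

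The comparisons with crotonic acid asked how the acid changed the cells on each day. At day 20, after 4 days, no gene passed edgeR's test among 17387 (2 libraries against 2; 585 had an unadjusted p under 0.05), and limma-voom and limma on FPKM gave 0, whereas DESeq2 gave 12. With the replicate block 6 genes passed. Calcb and Calca, neighbouring genes that encode calcitonin gene-related peptides, rose by 1.39 ± 0.16 (adjusted p = 0.0165) and 1.85 ± 0.23 (0.0296), the peptidase gene Ecel1 by 1.74 ± 0.22 and the laminin gene Lama5 by 1.12 ± 0.13, from 79.8 ± 15.1 to 173 ± 19.4 CPM. Col13a1, a transmembrane collagen, fell by 1.32 ± 0.18 and Aifm3 by 1.09 ± 0.12. All 25 measured extraembryonic endoderm genes failed to pass one by one, but 21 of them lay lower and camera called the list down (adjusted p = 0.000139; adjusted p = 0.908 with an estimated correlation). Col4a1, a basement membrane collagen, stood at 3608 ± 690 CPM with crotonic acid and 5160 ± 490 without. With the block 8 of the 25 fell when adjusted over the list alone. Camera also ranked proliferation genes lower (0.000783) and epithelial (0.0144) and p53 target genes (0.0316) higher, each with an adjusted p = 0.908 with an estimated correlation and no member called. The fit without the day 16 libraries, a setting chosen after the data were seen, gave 1 call and with the block 54, and the block without D20 + crotonic acid replicate 2 and D28 + crotonic acid replicate 1, which held liver transcripts, gave 0.

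At day 24 edgeR called 0 genes without the block (821 at an unadjusted p under 0.05; limma-voom and limma on FPKM 0; DESeq2 78; edgeR without a filter on low counts 162) and 93 with it, 41 higher and 52 lower. Slc7a11, the cystine transporter that feeds glutathione synthesis, rose in the blocked fit by 1.84 ± 0.24, from 28.1 ± 14.2 to 99.1 ± 27.9 CPM (adjusted p = 0.0071), Calcb by 2.34 ± 0.17, the calcium channel gene Trpv6 by 1.89 ± 0.27 and Apela, a peptide of early embryos, by 1.79 ± 0.21. Dio3, the deiodinase that inactivates thyroid hormone, rose by 1.85 ± 0.22, from 37.2 ± 5.50 to 138 ± 64.2 CPM. The noradrenaline transporter gene Slc6a2 fell by 2.07 ± 0.19, the transporter gene Slc26a10 by 2.29 ± 0.24, Col13a1 by 1.73 ± 0.18 and the growth factor Fgf3 by 1.61 ± 0.24. Of the 25 endoderm genes 4 fell with the block, among them Col4a1 by 0.76 ± 0.11 (adjusted p = 0.0116), Lamb1 by 0.65 ± 0.10 and Lama1 by 0.74 ± 0.13, and 10 when adjusted over the list alone. Cdx2 rose with the block by 1.70 ± 0.18 (adjusted p = 0.00359), 1 of 14 trophoblast genes to do so.

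Camera called the endoderm list down at day 24 (adjusted p = 1.09e-09) and the 2-cell (2.49e-12), muscle (0.00183), epithelial (0.00077) and cholesterol (0.0107) lists up. None held with an estimated correlation (adjusted p = 0.577 for the first 3, 0.839 and 0.82). With the block trophoblast (0.0178) and adipocyte genes (0.0215) passed upward as well, with adjusted p = 0.538 and 0.386 with an estimated correlation. In the 2-cell list 22 of 23 members lay higher and none was called; Zscan4d had 0.587 ± 0.388 CPM with and 0.0425 ± 0.0601 without the acid. Pou5f1 stood at 4.63 ± 0.295 CPM with and 1.997 ± 0.420 without (adjusted p = 1; with the block 0.277). Leaving out D24 + crotonic acid replicate 1 gave 1 call in place of 0, as did leaving out the day 16 libraries, which with the block gave 380.

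The 2-cell list had a median log2 change of 2.41 at day 24, where several members had few counts. There Zscan4d had 22 counts with and 2 without the acid, and Zscan4e 6 and 1. Among the lists at day 28, that of 2-cell genes had the largest median log2 change, at 2.111. All 23 measured members lay higher with crotonic acid, 21 of them passed when adjusted over the list alone, and none passed over all genes. Zscan4c stood at 13.98 ± 2.41 CPM with and 3.58 ± 1.29 without the acid, and Zscan4e at 5.50 ± 1.33 and 1.16 ± 0.234. With the block 3 members passed over all genes, Zscan4f, up by 2.37 ± 0.38 (adjusted p = 0.0473), and Zscan4d, up by 2.16 ± 0.34 (0.0316), among them. Camera called the list up with the preset (adjusted p = 1.61e-54) and with an estimated correlation (adjusted p = 0.0258; with the block 0.0446). The list did not pass at day 20 (0.817), averaged over days (0.258) or in the test of a difference between days 28 and 20 (0.432). Endoderm genes again lay lower (adjusted p = 1.2e-05; adjusted p = 0.712 with an estimated correlation), and with the block 3 of 25 fell, Lamb1 by 0.59 ± 0.10 and Col4a1 by 0.65 ± 0.11 among them. Cholesterol genes lay higher as a list (0.000627; adjusted p = 0.712 with an estimated correlation), although Insig1, which restrains the pathway, fell with the block by 0.59 ± 0.11 (adjusted p = 0.0432). Adipocyte genes lay higher (0.03; adjusted p = 0.292 with an estimated correlation), and germline genes passed with the block only (0.0291; adjusted p = 0.79 with an estimated correlation).

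Single genes at day 28 numbered 0 by edgeR (943 at an unadjusted p under 0.05), 6 by limma-voom, 1 or 0 by limma on FPKM with a pseudocount of 1 or 0.1, and 75 by DESeq2; with the block 52 rose and 55 fell. In the blocked fit Slc7a11 rose by 2.47 ± 0.24, from 19.5 ± 0.141 to 108 ± 5.38 CPM (adjusted p = 0.00255), Calcb by 2.49 ± 0.18 and the endothelial receptor gene Tie1 by 2.06 ± 0.29, and Slc6a2 fell by 2.18 ± 0.19, Fgf3 by 1.97 ± 0.25 and the prostaglandin receptor gene Ptger3 by 1.70 ± 0.25. Tert had 7.91 ± 1.76 CPM with and 5.24 ± 1.22 without the acid (adjusted p = 0.873; with the block 0.34), Pou5f1 20.0 ± 2.27 and 12.3 ± 3.59 (with the block 0.48), and Nanog 0.885 ± 0.471 and 0.854 ± 0.199. Alb, a liver gene chosen after its values were seen, stood at 68.8 CPM in replicate 1 and at 0 in replicate 2 with the acid. Without the day 16 libraries 1 gene passed and with the block 475; without both libraries that held liver transcripts 0 passed and with the block 3.

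Averaged over the 3 days, 6 libraries against 6, 105 genes rose and 75 fell with crotonic acid. Libraries with the same number deviated together across days, so the 6 per arm may not be independent. A deviation of a treated culture that lasted over days enters neither fit. The p-values and counts may therefore overstate the replication, with or without the block. Slc7a11 rose by 1.94 ± 0.21 (adjusted p = 0.00458), and Nqo1, a quinone reductase of the oxidative stress response, rose by 1.67 ± 0.19 (adjusted p = 0.00525). On each of the 3 days both treated libraries of either gene lay above both untreated ones. Ecel1 rose by 1.71 ± 0.22, the mitochondrial gene Rmdn2 by 1.5 ± 0.24, the neuronal genes Brinp1 by 1.49 ± 0.24 and Shank2 by 1.42 ± 0.19, the tight junction gene Cldn3 by 1.35 ± 0.24 and the hormone gene Sct by 1.25 ± 0.16. Slc6a2 fell by 1.84 ± 0.17 (adjusted p = 0.00217), from 91.0 ± 32.7 to 24.5 ± 3.60 CPM over the days, Slc26a10 by 1.79 ± 0.28, Galnt9 by 1.68 ± 0.31, Col13a1 by 1.55 ± 0.18, Fgf3 by 1.53 ± 0.22, Ptger3 by 1.41 ± 0.15, Fcgbp by 1.23 ± 0.22 and the calcium channel gene Ryr2 by 1.16 ± 0.14. With the block 732 genes rose and 558 fell, all 180 among them.

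Extraembryonic endoderm genes fell in 3 of 25 members over the days and in 8 when adjusted over the list alone: Lamb1 by 0.55 ± 0.10 (adjusted p = 0.0306), Col4a1 by 0.66 ± 0.13 (0.0494) and the endocytic adaptor gene Dab2 by 0.79 ± 0.15 (0.0435). With the block 10 fell, among them Lama1 by 0.58 ± 0.08, Gata4 by 0.36 ± 0.07 (adjusted p = 0.0117) and Gata6 by 0.52 ± 0.08 (adjusted p = 0.00549). Epithelial genes rose in 1 of 22 members (Cldn3) and with the block in 7, including Cdh1 by 0.58 ± 0.14 (adjusted p = 0.0297) and the protease inhibitor gene Spint1 by 0.54 ± 0.09. Among 21 cholesterol genes Dhcr7, the last enzyme of the pathway, rose by 0.60 ± 0.10 and Pmvk by 0.44 ± 0.08, while Insig1 fell by 0.47 ± 0.08. Of 14 trophoblast genes Tfap2c rose by 0.80 ± 0.16 (adjusted p = 0.0469), and with the block 4 rose and 1 fell, Cdx2 rising by 1.22 ± 0.10 and the keratin gene Krt7 falling by 1.11 ± 0.28. With the block 2 of 9 adipocyte genes rose, and 3 of 24 fibroblast genes rose and 1 fell, none of them called without it. Thy1 passed only with the block, higher by 1.10 ± 0.18 (adjusted p = 0.00522), in contrast to Col1a1, at 479 ± 194 CPM with and 520 ± 209 without the acid (adjusted p = 0.903; with the block 0.88). Utf1, a chromatin gene of pluripotent cells, also passed only with the block, at 1.27 ± 0.30 (adjusted p = 0.0284), while Pou5f1 (0.72 ± 0.42), Tert (0.41 ± 0.14), Sox2 (-0.39 ± 0.13) and Nanog (0.04 ± 0.26) passed in neither fit. The crotonyl-CoA hydratase gene Cdyl and the acyl-transfer gene Ep300 stood at 44.4 ± 8.73 and 95.8 ± 9.93 CPM with the acid. Without the acid they stood at 47.4 ± 9.49 and 95.5 ± 9.89 CPM (edgeR adjusted p = 0.858 and 0.989). None of 28 crotonylation and acylation genes passed without the block. With the block the acetyl-CoA synthetase gene Acss2 rose by 0.39 ± 0.07 (edgeR adjusted p = 0.00895) and the deacylase gene Sirt1 fell by 0.36 ± 0.10 (0.0476).

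Camera called the endoderm list down over the days (adjusted p = 5.85e-09) and cholesterol (0.00327), epithelial (0.00517) and adipocyte genes (0.0372) up, none of them with an estimated correlation (adjusted p = 0.774, 0.774, 0.844 and 0.646). The telomerase (0.93), shelterin (0.286) and acylation lists (0.682) did not pass, with no telomere gene called in either fit; Pot1a, which binds the telomeric single strand, had 20.5 ± 2.18 CPM with and 23.5 ± 1.22 without the acid. With the block p53 target genes (0.0261) passed upward and proliferation genes (0.0294) downward, each with an adjusted p = 0.846 with an estimated correlation and no member called. The count of 180 depended on single libraries: it was 24 without D20 replicate 1, 22 without D20 replicate 2, 92 and 27 without D24 replicates 1 and 2, and 56 without D28 replicate 2. Among treated libraries it was 44 and 54 without D20 + crotonic acid replicates 1 and 2, 38 and 42 without those of day 24, and 47 and 27 without those of day 28, and it was 3 without D20 + crotonic acid replicate 2 and D28 + crotonic acid replicate 1 together, the libraries with liver transcripts (516 with the block, 165 of the 180 among them). DESeq2 gave 619 calls, edgeR without a filter on low counts 1043, and the fit without the day 16 libraries 387.

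**Figure D2:**
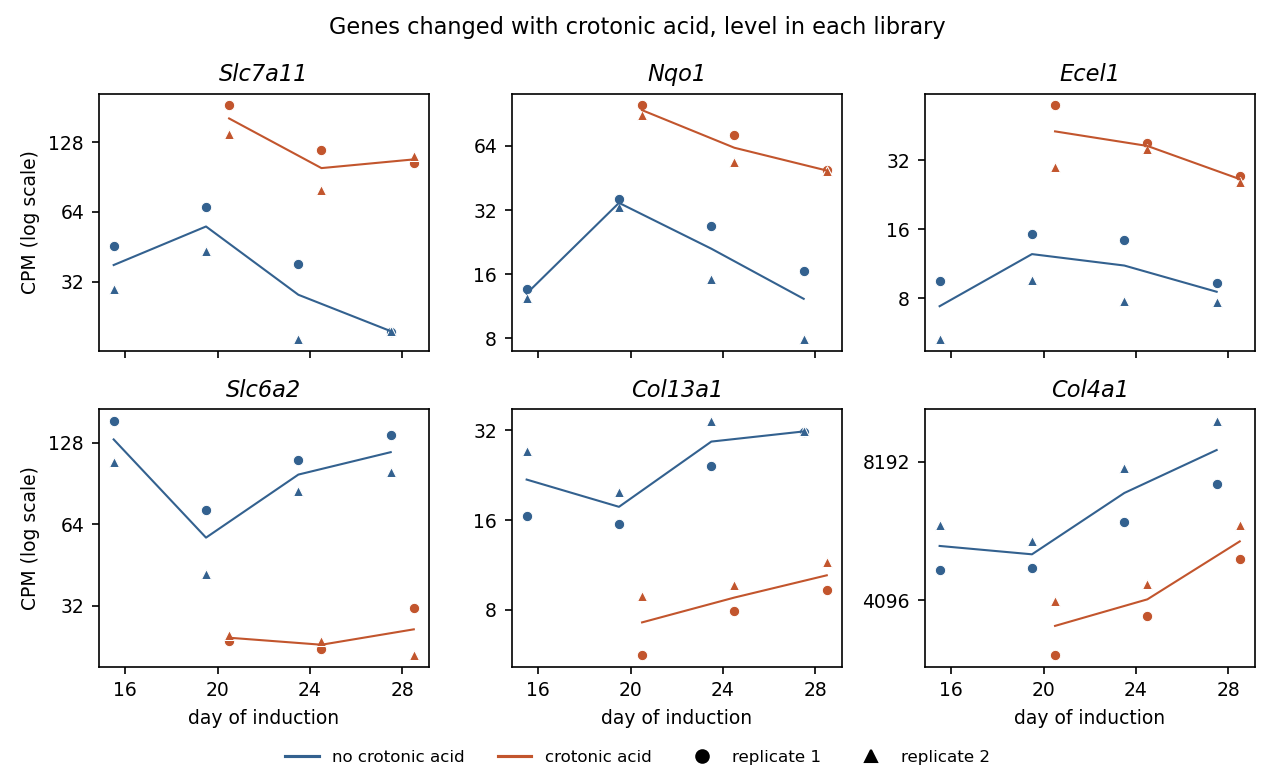
CPM on a log2 scale by day for Slc7a11, Nqo1, Ecel1, Slc6a2, Col13a1 and Col4a1, with a point per library and lines through the means of untreated and crotonic acid-treated cells. At day 28 Slc7a11 averages 108 CPM with and 19.5 CPM without the acid, and Slc6a2 26.2 and 118 CPM.

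A direct test of whether the effect differed between day 28 and day 20 called 0 genes by edgeR (184 at an unadjusted p under 0.05; 0 by DESeq2, limma-voom and limma on FPKM, and 0 with the block). For Zscan4d the difference in effect was 2.09 ± 2.5 (adjusted p = 1). Muscle genes differed as a list, higher at day 28 (camera adjusted p = 0.00211; adjusted p = 0.911 with an estimated correlation); Tnnt3, a troponin gene, had the smallest p among members (1.11 ± 0.64, adjusted p = 1). With the block glycolysis genes (down) and interferon genes (up) passed at 0.0141 each, with an adjusted p = 0.911 with an estimated correlation for both.

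The genes moved by the acid overlapped between days. At an unadjusted p under 0.05, days 24 and 28 shared 232 of 446 and 531 higher genes, where 13.6 were expected for independent lists (Fisher's exact p = 1.41e-246), and 190 lower genes, where 8.9 were expected. Only 6 shared genes over the 3 pairs of days went opposite ways, against 879 that went the same way. Among genes called with the block, 26 higher genes (Slc7a11 and Calcb included) and 32 lower genes (Slc6a2 and Col13a1 included) were shared by days 24 and 28, and without the block edgeR, with its filter on low counts, called no gene on any day. Each day had its own untreated libraries, although libraries with the same number deviated together across days. The days also shared an estimate of the spread for each gene, and genes that vary together are not independent. Fisher's exact p may therefore overstate the overlap.

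Every library was also placed on the axis from MEFs (0) to ES cells (1), by projection over all tested genes. Untreated cells stood at 0.401 ± 0.0636 at day 16, 0.465 ± 0.0224 at day 20, 0.507 ± 0.0249 at day 24 and 0.583 ± 0.0254 at day 28 (n = 2 each), the three-step line at 1.03 and both crotonic acid lines at 0.959 ± 0.0254. Treated cells stood at 0.454 ± 0.0270, 0.524 ± 0.0207 and 0.618 ± 0.0162. The mean difference within days was 0.0138 (exact permutation test within days, 2-sided p = 0.333; the smallest p possible was 0.00926), and with libraries paired by number the exact sign-flip p was 0.219 (smallest possible 0.0312). By day the difference was -0.0118, 0.0174 and 0.0357.

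**Figure D3:**
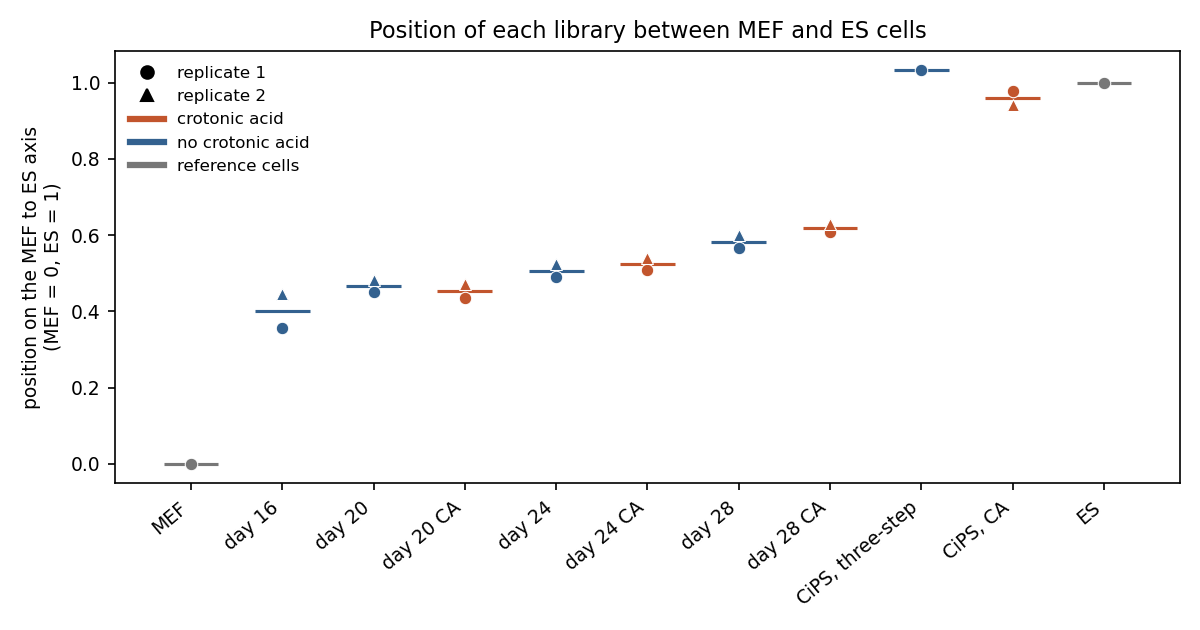
Position of each library on the axis from the MEF library (0) to the ES library (1), by day and treatment, with a point per library. Untreated cells average 0.401 at day 16 and 0.583 at day 28, treated cells 0.618 at day 28, and the 3 CiPS lines lie near 1.

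The next comparison set the established CiPS lines against untreated day 28 cells. Nanog rose by 9.29 ± 0.36, from 0.854 ± 0.199 to 540 ± 122 CPM (n = 3; adjusted p = 1.19e-09), Pou5f1 by 4.87 ± 0.35 to 360 ± 21.1 CPM, Klf2 by 7.04 ± 0.39 and Sox2 by 2.94 ± 0.24. Fgf4, a growth factor of the epiblast, was at least 3180-fold higher. In the naive list 24 of 26 genes rose and none fell. Extraembryonic endoderm genes fell in 21 of 26 members and 1 rose (Sall4, by 1.02 ± 0.32; adjusted p = 0.0954 for the list with an estimated correlation): Gata4 fell by 7.42 ± 0.44 to 4.50 ± 1.95 CPM, Sox17 by 8.81 ± 0.47, Foxa2 by 8.20 ± 0.34 and Col4a1 by 4.64 ± 0.20. The intestinal calcium-binding gene S100g went from 2070 ± 81.0 CPM to a single count over the 3 lines, and the water channel gene Aqp8 fell by 13.02 ± 0.40 from 892 ± 38.4 CPM.

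Of 11 telomerase genes 7 rose from day 28 to CiPS lines (adjusted p = 0.56 for the list with an estimated correlation), including Tert by 1.45 ± 0.25 to 14.4 ± 3.72 CPM (adjusted p = 0.000247) and dyskerin (Dkc1) by 2.57 ± 0.16, and Terf1 rose by 1.31 ± 0.20. Of 12 shelterin genes 4 rose and 2 fell. Of 24 recombination genes 15 rose and 3 fell (adjusted p = 0.717 for the list with an estimated correlation), with the chromatin remodeller Atrx at 2.10 ± 0.14 and Rad51d at -0.95 ± 0.11. The 2-cell genes rose in 27 of 28 members, Zscan4c by 4.28 ± 0.71 to 69.0 ± 55.7 CPM. Proliferation genes rose in 20 of 25 members, such as Mcm5 by 2.16 ± 0.31, and glycolysis genes in 15 of 21, such as Pgk1 by 2.38 ± 0.11. In the DNA methylation list 8 of 13 rose and 3 fell: Dnmt3l by 6.75 ± 0.53 and Tet1 by 4.64 ± 0.31 were among those that rose. Fatty acid oxidation genes fell in 10 of 18 members and rose in 2, and the acyl-CoA thioesterase gene Acot1 fell by 3.41 ± 0.27. Mesendoderm genes rose in 8 of 12 members and 1 fell: Nodal rose by 6.72 ± 0.72, and Eomes fell by 2.44 ± 0.38. Fibroblast genes, in contrast, rose in 14 of 24 members and fell in 3, with Col1a1 up by 4.33 ± 0.66 to 7755 ± 1370 CPM, near its 9364 CPM in ES cells, and Fn1 up by 2.76 ± 0.21, while Snai1 fell by 3.32 ± 0.22. Macrophage genes rose in 14 of 16 members, Laptm5 by 3.87 ± 0.38. Whether macrophage RNA came from the lines or from cells grown with them was not tested, here or in the comparisons of lines below.

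In all 5703 of 19597 genes rose and 5956 fell from day 28 to CiPS lines. Camera called 12 of the lists named here, all but shelterin, and the naive call alone held with an estimated correlation (adjusted p = 4.92e-21; adjusted p = 0.0201 with an estimated correlation). The endoderm list (2.08e-23) had an adjusted p = 0.0954 with an estimated correlation, and those of glycolysis (6.78e-07), 2-cell genes (2.86e-06), proliferation (0.000135), macrophages (0.00025), methylation (0.0109), fatty acid oxidation (0.0165), fibroblasts (0.0214), telomerase, recombination and mesendoderm (0.0249 each) had 0.291, 0.585, 0.649, 0.509, 0.291, 0.596, 0.717, 0.56, 0.717 and 0.291. For the shelterin list, with 4 of 12 members higher and 2 lower, the adjusted p was 0.345. Requiring a 2-fold change left 7752 genes.

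Against the MEF library, CiPS lines had every one of 26 naive pluripotency genes higher and every one of 24 fibroblast genes lower. The labels do not say that the lines came from these MEFs. Dppa5a stood at 1449 ± 155 CPM (n = 3) and was at least 10300-fold higher, Pou5f1 at least 2540-fold, Sall4 at least 2890-fold and Nr0b1, an orphan receptor of ES cells, at least 1530-fold. Col1a1 fell by 2.14 ± 0.63, Postn by 3.61 ± 0.28 and Twist1 by 3.16 ± 0.40. Among the genes with the largest falls the matrix collagen Col8a2 fell by 8.72 ± 0.44 and Agtr2, an angiotensin receptor, by 9.87 ± 1.35; Alb went from 49.3 to 0.0295 ± 0.0512 CPM, as one of the liver transcripts of the MEF library. Telomerase genes rose in 9 of 11 members and 1 fell, Tert by 1.49 ± 0.33 (adjusted p = 0.00204) and Dkc1 by 2.51 ± 0.22. Shelterin and CST genes, which cap telomeres, rose in 7 of 12 members and fell in 2, with Rif1 up by 4.15 ± 0.37 and Terf1 by 2.59 ± 0.29. All 28 2-cell genes rose, Zscan4d to 44.8 ± 32.4 CPM from 0. Recombination genes rose in 16 of 24 members (2 fell), for example Brca2 by 2.69 ± 0.29. Imprinted genes rose in 5 of 22 members and fell in 15. Those that fell included Cdkn1c by 7.46 ± 0.24, H19 by 4.69 ± 0.38 and Igf2 by 4.75 ± 0.32.

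Further lists differed between CiPS lines and MEFs. Epithelial genes rose in 16 of 22 members (1 fell), Cdh1 by 9.18 ± 0.55, while cholesterol genes fell in 20 of 21, Cyp51 by 1.79 ± 0.16. Germline genes rose in 17 of 22 (1 fell), Piwil2 by 5.48 ± 0.67, and proliferation genes in 19 of 25, Mcm2 by 2.25 ± 0.36. Glycolysis genes rose in 16 of 21, the glucose transporter gene Slc2a3 by 6.83 ± 0.87, muscle genes fell in 11 of 16 with 2 higher, the troponin gene Tnnt2 by 6.46 ± 0.55, and trophoblast genes rose in 7 of 14 (1 fell), Tead4 by 2.67 ± 0.31. Mesendoderm genes rose in 6 of 12, such as Eomes by 5.68 ± 0.93. Endoderm genes fell in 11 of 26 and rose in 6, with Col4a1 lower by 2.92 ± 0.21 and Gata6 by 2.38 ± 0.29.

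The totals were 5028 higher and 5377 lower among 19597 genes. Scaling by total counts put the median log2 change of all genes at 0.286, against 0.021 with TMM factors, and gave 6292 higher and 4183 lower genes. Camera called 16 lists. The naive (adjusted p = 1.46e-40; adjusted p = 0.00137 with an estimated correlation) and imprinted lists (1.73e-06; adjusted p = 0.0153 with an estimated correlation) held. Epithelial (2.38e-12), cholesterol (3.8e-09) and mesendoderm genes (0.00325) had an adjusted p = 0.137, 0.131 and 0.112 with an estimated correlation, and 2-cell (9.88e-09), fibroblast (7.06e-08), germline (1e-05), glycolysis (5.78e-05), telomerase (0.0052) and trophoblast genes (0.0165) had 0.378 each. For proliferation (0.000106), recombination (0.000532), muscle (0.0123), endoderm (0.0443) and shelterin genes (0.0443) it was 0.52, 0.443, 0.406, 0.588 and 0.458.

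The lines were then set against ES cells of the same strain (3 libraries against 1). Nanog stood at 540 ± 122 CPM in CiPS and 545 in ES cells, Sox2 at 468 ± 56.4 and 493, Pou5f1 at 360 ± 21.1 and 247, Tert at 14.4 ± 3.72 and 15.9 and Terf1 at 105 ± 14.6 and 83.5, with an adjusted p = 1 for each. Only 4 of 19597 genes passed, all higher in CiPS lines (589 had an unadjusted p under 0.05); limma-voom gave 1 higher and 3 lower, with Zfp229 alone in common. They were the X-linked Xlr3a (by 4.10 ± 0.49), Xlr3b (by 2.86 ± 0.33) and Xlr4a (by 5.44 ± 0.55, at 2.40 ± 0.124 CPM, chosen after its value was seen), near-identical copies that counting could mix, and the zinc finger gene Zfp229 (by 1.22 ± 0.16, adjusted p = 0.027). Dppa2, among the naive genes with the smallest p, had 91.6 ± 21.7 against 129 CPM.

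No member of any list passed in this comparison, but camera ranked interferon genes (adjusted p = 7.26e-16), inflammation genes (9.91e-08), 2-cell genes (1.16e-07), macrophage genes (1.32e-05) and fibroblast genes (0.00168) lower in CiPS lines. With an estimated correlation the adjusted p = 0.553, 0.553, 0.663, 0.553 and 0.758. The antiviral gene Oasl2 had 2.59 ± 0.891 against 9.06 CPM, the cytokine gene Il1a 0.745 ± 0.125 against 5.22, Zscan4d 44.8 ± 32.4 against 98.9, C1qa 16.2 ± 7.79 against 42.2 and Postn 267 ± 27.2 against 471. It ranked glycolysis and cholesterol genes (7.1e-05 each), epithelial (0.00355) and recombination genes (0.0468) higher, with an adjusted p = 0.553, 0.553, 0.758 and 0.758 with an estimated correlation; Pfkp had 331 ± 13.3 against 236 CPM, Stard4 54.8 ± 11.2 against 24.8, Dsp 29.1 ± 11.1 against 14.6 and Rad51c 12.2 ± 0.846 against 8.36. Leaving out the three-step line gave 10 higher and 3 lower genes, DESeq2 8 and 3 and a fit of the 4 compared libraries alone 0.

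Finally both lines made with crotonic acid were compared with the three-step line (2 libraries against 1), so a difference between methods cannot be separated from one between single lines. Here 7 genes were higher and 17 lower in the crotonic acid lines (1469 had an unadjusted p under 0.05). The neurofilament gene Nefm was higher by 3.24 ± 0.27 (46.8 ± 0.748 against 4.94 CPM, adjusted p = 0.00121), the imprinted gene Peg3 by 2.03 ± 0.27 and Gfra1, a receptor of glial-derived growth factor, by 1.25 ± 0.17. Dio3, an imprinted gene, was lower by 2.35 ± 0.31 (19.4 ± 1.94 against 98.8 CPM), the desaturase gene Scd3 by 2.20 ± 0.29, Tie1 by 2.29 ± 0.30, the chitinase gene Chit1 by 2.04 ± 0.30 and Ubd at least 145-fold. Rpl26, which has near-identical pseudogenes, was lower by 1.57 ± 0.18.

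The 2-cell genes lay lower in the crotonic acid lines in 27 of 28 members, 16 of them past the threshold when adjusted over the list alone and none over all genes. Zscan4c had 37.3 ± 12.9 against 132 CPM and Zscan4e 19.6 ± 5.08 against 76.5, and camera called the list down (adjusted p = 1.53e-29; adjusted p = 0.122 with an estimated correlation). Germline (2.57e-06), endothelial (0.00521) and trophoblast genes (0.0325) also ranked lower and interferon (3.88e-06), inflammation (0.000387), macrophage (0.000532), fibroblast (0.00222) and imprinted genes (0.0349) higher. With an estimated correlation these had an adjusted p = 0.499, 0.122, 0.499, 0.73, 0.73, 0.672, 0.73 and 0.499; of their members only Peg3 and the endothelial Tie1 passed, and Dio3, which is not on the imprinted list, moved the other way. Tert had 12.3 ± 1.29 against 18.6 CPM (adjusted p = 0.647) and Nanog 470 ± 32.0 against 678 (adjusted p = 0.702). Without either crotonic acid line (replicate 1 or replicate 2) 2 genes passed, and other settings gave up to 3437 (fit of the 3 lines alone), with 207 by DESeq2 and 231 by limma-voom.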

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

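Of the tests in this part, those on library size and on leftover fibroblast transcripts were chosen after their results were seen, and the NRF2 and ATF4 lists were written after Slc7a11 and Nqo1 were seen; H2-Q7, Eln and Ptn were also chosen after their values were seen. The effect of crotonic acid on the position between MEFs and ES cells differed between days: both replicate pairs lay lower with the acid at day 20 and both lay higher at day 28, and the effect at day 28 minus that at day 20 was 0.0475. That difference was not tested. The muscle list differed between day 28 and day 20 in a test of the difference itself (camera adjusted p = 0.00211; adjusted p = 0.911 with an estimated correlation).

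Slc7a11 and Nqo1, higher with crotonic acid on every day, are both known targets of NRF2, and Slc7a11 also of ATF4. ATF4 induction is argued against: the median log2 change of 16 listed targets was -0.285 with the block, and 6 of them fell there (1 without the block). A difference in library size is argued against too, since mean total counts with and without the acid had a ratio of 1.006 at day 28, where Slc7a11 and Nqo1 were higher by log2 changes of 2.47 and 2. NRF2 induction stays open: 18 other targets had a median of 0.204, barely over the 0.2 set for it, with 15 above 0, 2 called with the block and none without (camera p = 1.55e-05 with the block, 0.0385 with an estimated correlation). Crotonic acid itself is the design's biological difference, and no measurement here separates its chemical from its metabolic effects.

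Libraries of the first and second replicate sets differed in 5484 genes, with H2-Q7 at no more than 0.051 CPM in every first library and 3.15 to 24.8 CPM in every second one. A set ahead in time is argued against as the whole cause, since the correlation across genes with the change from day 16 to day 28 was 0.051; a small lead stays open, since the second library lay further from MEFs towards ES cells in all 7 groups (0.6006 against 0.5648 at day 28). Haplotypes that differ between the sets cannot be told apart from other causes: 107 pairs of strongly different genes were chromosomal neighbours, over the 50 reached by shuffles but under the 139 of genes changed with time. On chromosome 17 from 33 to 38 Mb, where H2-Q7 lies, 12 of 149 tested genes were strongly different, against 737 of 17311 with a known position. Near-identical H2-Q genes were among the 12. Gene length or GC bias stays undecided as well, with a largest correlation of 0.134.

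Fibroblast genes were high in CiPS lines and in ES cells, with Col1a1 at 7755 and 9364 CPM. Transcripts left over from the starting cells gave no excess over ES cells, since the listed genes lay lower in CiPS lines than in ES cells, with a median of -0.277. That comparison cannot exclude leftover transcripts, because the ES library held such RNA too, with Col1a1 at 27.4% of its MEF level. RNA of fibroblasts grown with the lines stays open: on average 9.7% of 114 abundant MEF genes stood under 0.1 of the share of its MEF level that Col1a1 had (18.8% to 27.4%). Fibroblasts identical to the sequenced MEFs cannot account for Eln, at 12.3 to 23.3 CPM against 5287 in MEFs, or Ptn, at 26.9 to 81.4 CPM against 2992, both far under the share of Col1a1. The lines' own expression of these genes, the biological explanation, was not tested.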

How the results depend on the processing

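The fits without the day 16 libraries and without the libraries with liver transcripts were chosen after the results were seen; the other settings were planned. No named gene that was called in the main fit or in the setting compared reversed its direction there. Changes of sign in genes called in neither were not counted. The balance of higher and lower calls did turn over in some settings. From MEFs to CiPS lines it was 5028 higher and 5377 lower, but 6292 and 4183 with total-count scaling. For CiPS lines against ES cells it was 4 and 0, but 1 and 3 with limma-voom. RLE factors changed no count by more than 1.5 times. The position between MEFs and ES cells and the difference between days 28 and 20 kept their side of the threshold in every setting run. Total-count scaling gave 1 gene at day 20 of crotonic acid in place of 0, and 39 between the CiPS lines by method in place of 24. Without a filter on low counts, the counts for days 20, 24 and 28 were 45, 162 and 249, for the mean over days 1043, for CiPS lines against ES cells 9 and for the lines by method 159. DESeq2 gave 12, 78, 75, 619, 11 and 207 for the same results, and the cause was not tested. Limma-voom gave 6 at day 28 and 231 by method. FPKM with a pseudocount of 1 gave 1 at day 28, 1877 from day 16 to day 28 and 149 by method; a pseudocount of 0.1 gave 1903 from day 16 to day 28, both on fewer genes tested. The 2-fold threshold left 78 for the mean over days and 7752 from day 28 to CiPS lines. Fits of the compared groups alone, which have fewer samples, gave 1 at day 28, 387 for the mean over days, 401 from day 16 to day 28, 1821 from MEFs to day 16, 0 for CiPS lines against ES cells and 3437 by method.

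The replicate block gave 6, 93 and 107 at days 20, 24 and 28, 1290 for the mean over days and 5394 from day 16 to day 28, since it takes a shared deviation of libraries out of the spread; it ended no call of a named gene, left the difference between days 28 and 20 at 0 genes, and changed no list result other than those given with it in the report. Without the day 16 libraries the counts were 1, 1, 1 and 387 for days 20, 24, 28 and their mean, and with the block 54, 380, 475 and 2317; the cause was not tested. Without the 2 crotonic acid libraries with liver transcripts the mean over days fell to 3 genes, all among the 180, and with the block it was 516, with 3 at day 28; fewer samples were used there. With an estimated correlation 6 list results passed in place of 82 (68 with fry). The block was run in 6 comparisons, where 35 list results passed in place of 27. Calls shared between days, summed over pairs of days so that a gene can count more than once, numbered 0. They were 879 at an unadjusted p under 0.05 and 70 with the block.

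Leaving out 1 library at a time gave 0 to 0 genes at days 20 and 28 and for their difference, 0 to 1 at day 24, 22 to 179 for the mean over days, 1553 to 3325 from day 16 to day 28, 5512 to 6848 from MEFs to day 16, 9549 to 10975 from day 28 to CiPS lines, 9441 to 9814 from MEFs to CiPS lines, 3 to 13 for CiPS lines against ES cells and 2 to 2 by method; the mean shift in position was 0.0074 to 0.0201. Where this left 1 library in a group, that library was assumed to vary like the others.

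Within-day exchanges of labels had 108 splits, of which 100 were drawn. In 2 of them, the real one included, at least 180 genes passed; the other one, with 1464, followed the replicate number. Among 30 drawn splits that part every replicate pair, the real one gave 180 and the others 0. With the block, over 32 such splits, the real one gave 1290 and the highest other 24. Labels were exchanged on each day separately, so these splits cannot exclude a difference between cultures that lasted over the days. Over 245 named gene results and all settings, 3317 values kept their side of the threshold, 258 calls ended and 208 were added; of 308 list results, 948 values kept it, 113 calls ended and 31 were added. Depth limits mainly genes of few counts, such as the 2-cell genes before day 28.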

Other observations

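The genes described in this part and the liver genes were chosen after their values were seen, except the members of lists and the fixed genes. Histone acylation genes changed between day 28 and CiPS lines (n = 3 against 2), with 11 of 28 members higher and 9 lower. The deacylase gene Sirt1 rose by 3.01 ± 0.20 to 169 ± 1.51 CPM (edgeR adjusted p = 7.18e-08), Cdyl2, a paralog of the crotonyl-CoA hydratase gene Cdyl, rose by 3.20 ± 0.27, and the deacetylase gene Hdac1 rose by 1.55 ± 0.13, while Sirt2 fell by 1.51 ± 0.13 to 37.4 ± 3.67 CPM. The list as a whole did not pass (camera adjusted p = 0.379). Against MEFs 9 members rose and 7 fell, among them Cdyl2, up by 3.09 ± 0.37, and Mllt1, a reader of acylated histones, which fell by 1.11 ± 0.14. From MEFs to day 16 the reader gene Mllt3 rose by 1.84 ± 0.20 and the crotonyl-CoA hydratase gene Echs1 fell by 0.51 ± 0.13, 2 of 7 members past the threshold.

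Alb and Fga, genes of adult liver, were highest in 3 of 19 libraries. Alb stood at 49.3 CPM in MEFs, 25.8 CPM in D20 + crotonic acid replicate 2 and 68.8 CPM in D28 + crotonic acid replicate 1, and at no more than 0.273 CPM in the other 16 libraries. Fga stood at 5.41, 1.77 and 8.14 CPM in the same 3 libraries. Afp, a gene of fetal liver and yolk sac, reached no more than 0.705 CPM in any library. None of the 11 listed adult genes was called for crotonic acid averaged over days, with or without the block.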
